A study of Mus musculus with 8 samples.

How the data were processed

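Liver RNA of WT and KO mice, all given tunicamycin at 2 mg/kg for 24 hours, was measured by sequencing of polyadenylated RNA before and after m6A immunoprecipitation, with 2 libraries per group of genotype and library type. The submitters' processing notes name HISAT2 2.1.0, DESeq2 1.18.1 and the mm10 build. The read counter, the gene annotation and the m6A peak caller with its settings are not given in the sources used here.

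The authors deposited 1 table of their own comparison of the input libraries and 1 peak list per genotype. In the deposited table the mean per gene is a signal, the mean over 4 libraries of counts divided by size factors. Its fold change and standard error are in log2 units, per the file headers. Its test value is a score, the Wald statistic of DESeq2, and its p-value and adjusted p-value are those of the authors, for 14257 of 16133 genes. Benjamini-Hochberg adjustment computed anew gave the deposited adjusted values. In the deposited peak lists the enrichment is taken as a ratio of antibody-enriched over input RNA, and a second value per peak, between 0 and 1, is taken as the authors' p-value, with no statement of whether it was adjusted. The deposited lists gave 1 value per peak and genotype. The genotype that forms the numerator of the fold change is not stated, and it was read as KO over WT from the peak lists, as described with the results.

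Counts per library were recovered from the digits of the deposited means. Each mean is a sum of 4 whole read counts, each multiplied by a step of its own library, and the lowest means gave these steps and hence size factors of 1.25, 1.18, 0.927 and 0.743. For each gene with a mean of at most 10000 the whole numbers that give its mean were searched, with the deposited fold change as a guide where the mean was above 100. Counts were found for 15949 genes (98.9%), of which 6931 were found without the fold change. For 1333 genes with a mean above 50 whose counts were found without the fold change, fold changes fitted anew from the counts differed from the deposited ones by a median of 6.49e-07 and at most 0.00486 on the log2 scale; for genes above a mean of 100 such a comparison is no independent check. On simulated libraries 785 of 785 genes were recovered correctly. The 181 genes above that mean and 3 others were left out of every analysis of single libraries, which removes many of the most abundant liver mRNAs. Libraries are called KO A, KO B, WT A and WT B, since their replicate number cannot be told from the values. Estimated totals were 12301610 to 16822807 reads per input library, with the unrecovered genes set to the deposited mean of their genotype. Within genotypes the correlation of log2 counts across genes was 0.98 (KO) and 0.97 (WT), and between genotypes 0.83 to 0.84; genes are not independent replicates.

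Genes were counted as higher or lower in KO at a deposited adjusted p under 0.05. Before the data were examined, 28 gene lists with 598 genes, the named genes, the tests and most of the alternatives were chosen; 27 lists had at least 5 tested members, and the list of mitochondrially encoded genes had 0 in the table. For each list the median log2 change was compared with 10000 random lists of the same size drawn within 20 bins of mean expression (two-sided, smallest possible p 0.0002), and rises against falls with all other tested genes by a two-sided Fisher's exact test, each adjusted over the 27 lists by the Benjamini-Hochberg method. On simulated lists of 20 genes, 2.5% of 40 lists were called without a shift, 32.5% with a shift of 0.5 and 95% with a shift of 1. Genes of these simulated lists were independent. Members of the real lists can vary together, so 2.5% need not be the rate of false calls on them. Chosen after the data were seen, limma 3.58.1 with a trend was fitted to log2 of the recovered normalized counts plus 1. Camera, also chosen then, was run on that fit with a preset correlation of 0.01 and with an estimated correlation. With 2 libraries per genotype the estimated setting has few degrees of freedom and can hardly call a list. With 200 changed genes simulated among 14073, limma called 82% of those with a log2 change of 1, 100% of those with a change of 2 and 0.108% of unchanged genes. The simulated genes were independent, shared 1 dispersion and seldom changed, so these rates need not hold for the real libraries.

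Genes are named in the text by a rule: Mettl14, the other measured writers and 10 genes of the unfolded protein response in any case; the 8 largest rises and 8 largest falls among called genes above the median mean count, without predicted genes; up to 4 called members with the smallest p per list, or 2 where none passed; for peaks, Ddit3 and the PERK list, the 5 highest scores per list, and the 5 genes with the highest scores among those with peaks in 1 list alone. Further genes are named as list members, or as named after their values were seen.

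Peaks were compared block by block with bedtools 2.31.1, with an overlap of at least 1 bp counted as shared. Peaks were placed by the start and end of their gene in the RefSeq annotation of the build, within 1000 bp of either or farther from both; 95.7% of WT and 95.5% of KO peaks could be placed. Repeated intervals (1 in WT, 3 in KO) and peaks with a p above 0.05 (32 and 3) were kept. Shares carry exact 95% Clopper-Pearson intervals, which cover counting error only. Log2 changes of peak classes were compared by two-sided permutation of class within 10 bins of mean expression, 100000 times for each of 5 comparisons. In simulations of independent genes this test called 6.5% of 200 runs without a shift and 99% with a shift of 0.3.

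Alternatives were an adjusted p under 0.01, an at least 2-fold change, genes above the median mean count alone, limma with pseudocounts of 1 and 0.1, limma with total-count scaling, limma without each library in turn, unmatched random lists, peaks with a smaller p, peaks with an enrichment of at least 4, an overlap of at least 0.5 of the shorter peak, equal numbers of top peaks, genes in place of peaks, bounds of 500 and 2000 bp, differences of means, and comparisons without bins. A fit without a library leaves 1 library in its genotype, assumed to vary like the others. Sequence motifs and untranslated regions were not analysed here, since no genome sequence and no transcript models were used. Computations used Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9) and R 4.3.3.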

Results

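Liver RNA was compared between mice lacking METTL14 in the liver (METTL14Alb, here KO) and floxed mice without the deletion (here WT). METTL14 is the partner of METTL3 in the complex that writes N6-methyladenosine (m6A) into mRNA. All mice had received tunicamycin, which blocks N-linked glycosylation and so causes stress of the endoplasmic reticulum (ER), at 2 mg/kg for 24 hours. Polyadenylated RNA was sequenced before antibody enrichment (input) and after precipitation with an m6A antibody (IP), with 2 libraries in each of the groups WT input, KO input, WT IP and KO IP. Levels without tunicamycin were not measured in this series. The labels do not say whether the libraries of a group came from separate mice, so the p-values measure only the spread between these libraries. The files held 1 comparison of the input libraries and 1 list of m6A peaks per genotype. Read counts of the 4 input libraries, recovered from the deposited mean counts for 15949 of 16133 genes, gave estimated totals of 12680375 reads in KO A, 12301610 in KO B, 16822807 in WT A and 13497014 in WT B. The depth of the IP libraries is not given in the sources used here.

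The header of the comparison does not say which genotype is the numerator, and every direction below rests on a reading of it as KO over WT. The peak lists decided that reading, on the ground that peaks are called more readily where an mRNA is abundant. Among 347 genes with a mean count of at least 100 and a value above 2 in the authors' deposited table, 156 had a peak in the KO list alone and 0 in the WT list alone. Among 403 such genes below -2, 30 had a peak in the KO list alone and 46 in the WT list alone (two-sided Fisher's exact test, p = 1.31e-28).

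The first question was whether the targeted gene was lower in KO liver, and the mRNA of Mettl14 was not detectably so. In the authors' deposited table the log2 change of Mettl14 (chromosome 3, 123368295 to 123385990, mm10) was -0.50 ± 0.41 (SE), with an adjusted p of 0.342 from DESeq2. Normalized counts of Mettl14 were 64.6 and 62.0 in the KO libraries and 79.8 and 99.7 in the WT libraries, so the genotypes did not overlap but the counts were low. Neither peak list held a peak in Mettl14. With libraries scaled to equal total counts the log2 change of Mettl14 was 0.32 in limma (adjusted p = 0.306), the opposite sign. The median over all genes of that fit was 0.87, so Mettl14 still lay below the typical gene. Other cell types of the liver, and any reads outside a deleted exon, could count toward this gene in bulk tissue. Neither was analysed here.

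Few other writers of m6A passed the test at the authors' size factors. Of 11 tested writers 2 rose and 1 fell (2 and 1 adjusted over the list alone). In the authors' deposited table Mettl16 rose by 0.92 ± 0.29 (SE, adjusted p = 0.00426), Rbm15 by 0.78 ± 0.25 (adjusted p = 0.00644), and Mettl5 fell by 0.83 ± 0.33 (adjusted p = 0.0283). METTL16 methylates U6 and MAT2A RNA, RBM15 guides the writer complex to mRNA, and METTL5 methylates ribosomal RNA. The same authors' deposited table gave 0.17 for Mettl3 (adjusted p = 0.677) and 0.17 for Wtap (adjusted p = 0.591). Of 14 tested erasers and readers 3 rose and 1 fell (2 and 1 adjusted over the list alone). Ythdf2, a reader that recruits the deadenylation machinery, rose 2.84-fold in the authors' deposited table (SE 0.21 on the log2 scale, adjusted p = 1.68e-11), and the readers Ythdf1 (0.61) and Prrc2a (0.45) rose less. Hnrnpc, which binds RNA opened by m6A, had a log2 change of -0.79 there, which turned to 0.033 with total-count scaling. Neither list lay apart from random lists matched on mean expression (adjusted p = 0.871 for writers and 0.110 for erasers and readers; camera with an estimated correlation, adjusted p = 0.7996 for both). With total-count scaling limma called 9 writers higher and 0 lower, and 13 erasers and readers higher and 0 lower. That fit called 8258 of all 14073 genes higher and 1064 lower, so these counts largely follow a shift of most genes.

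The second question was how the liver transcriptome under tunicamycin differed by genotype, and it differed widely. Of 14257 tested genes 6066 (42.5%) passed an adjusted p of 0.05 in the authors' deposited table, with 2904 higher and 3162 lower in KO, so that 47.9% of the called genes were higher. At least 2-fold changes were found in 2131 genes upward and 1801 downward, and at least 16-fold changes in 298 upward and 80 downward. Among recovered genes with a mean count of at least 10, 78.9% of 12663 had no overlap between genotypes, against 33.3% by chance. Scaling to total counts moved the median log2 change by 0.80 and left 88.6% of the called genes higher. The balance of rises and falls below is therefore relative to the authors' size factors. Counts and medians of lists by total-count scaling stand beside 8258 of 14073 genes called higher, 1064 called lower and a median of 0.87 over all genes. A limma fit without 1 library takes its spread from the 2 libraries of the other genotype alone. How many genes it called depended strongly on which pair that was, with far fewer calls where a KO library was left out. Such counts do not measure how far a result rests on 1 library. All of the authors' calls that could be recomputed kept their sign without each library.

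The largest rises among genes above the median mean count were of genes with low counts in WT. Ly6d, a small membrane protein of the LY6 family, rose by 7.69 ± 0.34 (SE) on the log2 scale in the authors' deposited table (adjusted p = 3.21e-112), from normalized counts of 16.2 and 18.9 in WT to 4006 and 3170 in KO. The next were Slc24a3 (7.23), Rin1 (6.05), Col20a1 (5.70), Fchsd1 (5.55), Abcc4 (5.29), Cd276 (5.22) and Cib3 (5.07) in the authors' deposited table. The 8 largest falls were all of major urinary proteins, pheromone carriers secreted by the liver, led by Mup17, Mup12, Mup15 and Mup7 at -11.87, -11.19, -11.07 and -11.05 in the authors' deposited table. All 15 tested members of the Mup list fell (15 adjusted over the list alone), with a median of -9.51 against -0.68 for random lists. The permutation p, adjusted over 27 lists, was 0.0006, from the smallest p these lists can give. Camera with an estimated correlation gave an adjusted p of 0.492. Mup genes are near copies of each other and share reads, so values of single Mup genes are uncertain. Their level also differed between the WT libraries, as for Mup17 with normalized counts of 17954 and 5942.

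Targets of the PERK arm of the unfolded protein response, in which ATF4 and CHOP induce amino acid and cell death genes, lay above comparable genes in KO. Of 30 tested members 11 rose and 5 fell (12 and 6 adjusted over the list alone), with a median log2 change of 0.77 against -0.34 for matched random lists (adjusted permutation p = 0.0006). Camera gave the list an adjusted p of 0.0422 with a preset and 0.790 with an estimated correlation, and Fisher's exact test of rises against falls gave an adjusted p of 0.198. In the authors' deposited table the stress regulator Nupr1 rose by 3.01 ± 0.20 (adjusted p = 6.06e-49), the amino acid transporter subunit Slc3a2 by 1.95 ± 0.22 (adjusted p = 4.32e-18), and Ppp1r15a, which restores translation by dephosphorylating eIF2α, by 1.63 ± 0.25 (adjusted p = 1.13e-09). The transcription factor Atf3 rose by 3.46 ± 1.34 in the authors' deposited table (adjusted p = 0.0254), with normalized counts of 1764 and 3293 in KO and of 47.4 and 413 in WT, and in limma by 2.54 without WT A and 5.64 without WT B. Members also fell, among them Atf5 (-2.34), the cysteine-forming enzyme Cth (-2.01) and the stress hormone Fgf21 (-3.09 ± 0.59, adjusted p = 1.41e-06) in the authors' deposited table.

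Ddit3, which encodes CHOP, did not pass the test. Its log2 change was 1.24 ± 0.66 (SE) in the authors' deposited table (adjusted p = 0.117), with normalized counts of 3258 and 2972 in KO against 723 and 1919 in WT. Limma on the recovered counts called Ddit3 (log2 change 1.40, adjusted p = 0.0211, and from 6.29e-06 to 0.310 over its other limma fits). Atf4 had a log2 change of 0.05 and Trib3 one of 0.41 in the authors' deposited table (adjusted p = 0.902 and 0.173). The WT libraries stood apart from each other in this group. Of 27 recovered PERK targets with a mean count of at least 10, 24 were higher in WT B than in WT A, 10 of them at least 2-fold, with a median log2 ratio of 0.60. Between KO B and KO A that median was 0.01 and 0 members were 2-fold apart. Without WT A the limma median of the list was 0.56 and Atf4 turned to -0.42, and without WT B the median was 1.31.

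**Figure D1:**
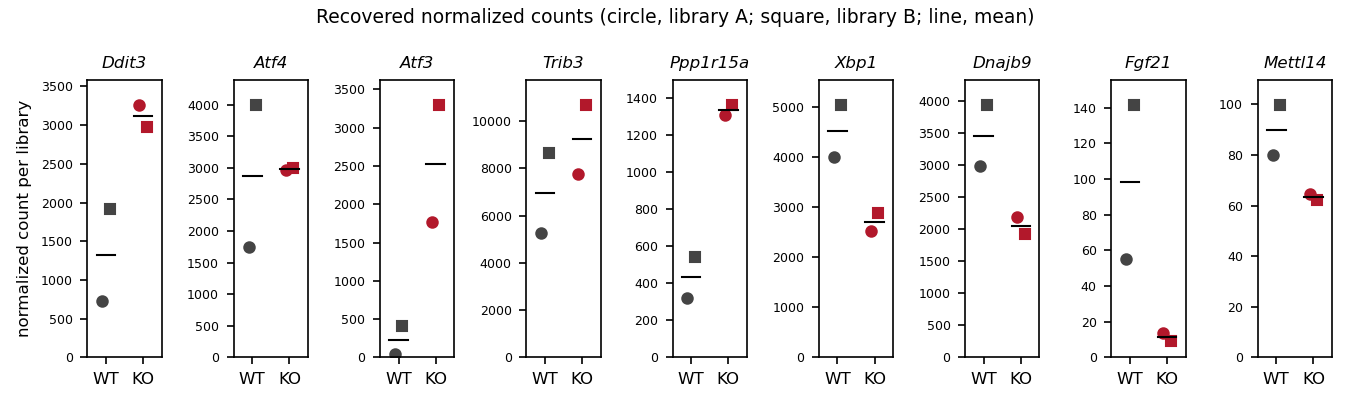
Normalized counts per input library recovered for 8 stress genes and Mettl14, with WT in grey, KO in red and a line at the mean of the 2 libraries (circle, library A; square, library B). Ddit3 stood at 723 and 1919 in WT and at 3258 and 2972 in KO, while Atf4 spanned 1750 to 3989 in WT, around its KO values.

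Lists of the IRE1 and ATF6 arms of the unfolded protein response held more falls than rises at the authors' size factors, and their medians did not lie apart from those of random lists of like expression. Hspa5, the ER chaperone BiP, rose by 1.36 ± 0.20 (SE) on the log2 scale in the authors' deposited table (adjusted p = 3.35e-10). Herpud1, a membrane protein of ER-associated degradation, fell by 2.37 ± 0.19 there (adjusted p = 2.69e-35), and Xbp1 and its target Dnajb9 had values of -0.74 ± 0.19 and -0.75 ± 0.20 in the authors' deposited table (adjusted p = 5.86e-04 and 8.41e-04). Both Xbp1 and Dnajb9 turned positive with total-count scaling (0.085 and 0.080). Of 26 targets of IRE1 and XBP1, 1 rose and 19 fell (2 and 20 adjusted over the list alone), among them the secretory pathway genes Serp1 (-1.40), Sdf2l1 (-1.38), Kdelr2 (-1.26) and Dnajb11 (-1.12) in the authors' deposited table. Of 21 targets of ATF6 and ER chaperones, 2 rose and 12 fell (2 and 12 adjusted over the list alone), with Derl3 at -1.75, Sdf2 at -1.69 and Ppib at -1.42 in the authors' deposited table. Of 25 genes of ER-associated degradation, 1 rose and 18 fell (1 and 18 adjusted over the list alone), led by the ubiquitin ligase Rnf5 (-2.27) and by Derl2 (-1.61) in the authors' deposited table.

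These ER lists held more falls than all other tested genes (Fisher's exact test, adjusted p = 2.72e-04 for IRE1 and XBP1 targets, 0.0251 for ATF6 targets and 3.62e-04 for degradation). Their medians of -0.77, -0.48 and -0.96 did not lie apart from those of random lists matched on mean expression, at -0.68, -0.87 and -0.63 (adjusted permutation p = 0.742, 0.198 and 0.198). Genes above the median mean count had a median of -0.24 in the authors' deposited table. Over the 24, 9 and 22 recovered members of these lists the limma medians were -0.76, -0.78 and -0.93. With total-count scaling those of the IRE1 and ATF6 lists turned to 0.057 and 0.044 and that of the degradation list was -0.11. Limma then called 6, 3 and 6 rises beside 4, 2 and 6 falls. Camera gave adjusted p = 3.15e-04, 0.0266 and 9.09e-05 with a preset and 0.754, 0.492 and 0.575 with an estimated correlation, with 9 of the 21 ATF6 list members recovered for it.

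Most tested targets of p53 rose in KO. Of 18 tested members 15 rose and 0 fell (15 and 0 adjusted over the list alone; 15 of 18 also rose in limma), with a median of 1.69 against -0.06 for matched random lists (adjusted permutation p = 0.0006; camera with an estimated correlation, adjusted p = 0.492). In the authors' deposited table Phlda3, an inhibitor of AKT, rose by 4.64 ± 0.40 (SE), the cell cycle inhibitor Cdkn1a by 2.56 ± 0.24, the RNA-binding protein Zmat3 by 2.48 ± 0.25 and the kinase Plk2 by 3.39 ± 0.36. Apoptosis regulators overlapped that list: 9 of 22 rose and 1 fell (9 and 4 adjusted over the list alone), with a median of 0.72 against 0.09 (adjusted permutation p = 0.0320; camera with an estimated correlation, adjusted p = 0.492). Bax rose by 1.80 and the death receptor Tnfrsf10b by 5.38 in the authors' deposited table, and so did the survival gene Bcl2l1 by 1.54, while Cflar, which blocks caspase 8, fell by 0.83. The genes Bax, Bbc3, Fas and Tnfrsf10b stood in both of these lists.

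Cell cycle genes lay above comparable genes in KO, as did p53 targets and markers of bile duct and stellate cells. Of 25 tested members 14 rose, 10 were not called and 1 fell (14 and 1 adjusted over the list alone), Tk1 at -1.96 in the authors' deposited table, which was named after its value was seen, with a median of 2.83 against 0.43 for matched random lists (adjusted permutation p = 0.0006; camera with an estimated correlation, adjusted p = 0.575). The proliferation marker Mki67 rose by 5.06 ± 0.56 (SE), the replication helicase subunits Mcm2 by 3.46 ± 0.37 and Mcm6 by 3.41 ± 0.44, and Ccnd1 by 2.46 ± 0.31 in the authors' deposited table. The KO libraries differed in this group. Of 23 recovered members with a mean count of at least 10, 5 were at least 2-fold apart, as for Mki67 with normalized counts of 352 and 169. Targets of NRF2, the regulator of antioxidant and glutathione genes, also lay above comparable genes, with 10 of 23 higher and 3 lower (11 and 3 adjusted over the list alone) and a median of 0.59 against -0.27. Their adjusted permutation p was 0.00196, Fisher's exact test gave an adjusted p of 0.0833, and camera with an estimated correlation an adjusted p of 0.790. The exporter Abcc4 rose by 5.29, the glutathione transferases Gsta2 by 3.32 and Gstm3 by 2.05, and Pgd of the pentose phosphate pathway by 1.77 in the authors' deposited table.

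Markers of bile duct and progenitor cells and of stellate cells lay above comparable genes in KO. Of 19 cholangiocyte and progenitor markers 12 rose and 0 fell (14 and 0 adjusted over the list alone; 15 rose in limma), with a median of 2.83 against 0.31 (adjusted permutation p = 0.0006; camera with an estimated correlation, adjusted p = 0.492). The duct keratin Krt19 rose by 3.59 ± 0.46 (SE), Tspan8 by 3.65 ± 0.47, Epcam by 3.54 ± 0.48 and Spp1 by 2.24 ± 0.22 in the authors' deposited table. Of 19 fibrosis and stellate cell markers 14 rose and 0 fell (14 and 1 adjusted over the list alone; 13 rose in limma), with a median of 1.82 against -0.10 (adjusted permutation p = 0.0006; camera with an estimated correlation, adjusted p = 0.650). The collagens Col1a1, Col3a1 and Col1a2 rose by 4.08, 4.02 and 2.72 and the contractile gene Tagln by 3.23 in the authors' deposited table.

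Of 20 macrophage markers 5 rose and 2 fell (5 and 2 adjusted over the list alone), and the median of 0.11, which was -0.090 among genes above the median mean count, was not apart from random lists (adjusted permutation p = 0.742). In limma the macrophage median was 0.12, and 0.048 without KO A, 0.29 without KO B, 0.080 without WT A and 0.40 without WT B (8 higher and 3 lower). Cd68, Gpnmb and Cd14, all expressed by macrophages, rose by 3.65, 4.94 and 2.44, while the Kupffer cell lectin Clec4f fell by 1.39 in the authors' deposited table. With total-count scaling limma called 12 of 20 macrophage markers higher and 0 lower (median 0.94). Of 14 endothelial markers it called 12 higher and 0 lower (median 0.90). Over all genes that fit called 8258 of 14073 higher, with a median of 0.87. Spp1 stood in both the macrophage and the cholangiocyte list. Of 14 endothelial markers 0 rose and 1 fell (0 and 0 adjusted over the list alone), namely Clec4g at -0.54 in the authors' deposited table (adjusted p = 0.0464), which turned to 0.27 with total-count scaling. Their median was 0.06 (adjusted permutation p = 0.785). Of 9 neutrophil markers 1 fell, Retnlg at -2.20 in the authors' deposited table (none adjusted over the list alone), and of 10 erythroid markers 1 fell, the transcription factor Klf1 at -3.43 in the authors' deposited table (1 adjusted over the list alone). The medians of these lists, -0.13 and -0.68, turned positive with total-count scaling (0.78 and 0.22) and were not apart from random lists (adjusted permutation p = 0.214 and 0.464). Single libraries also turned these medians: without KO B the neutrophil and erythroid lists had 0.41 and 0.69, without WT B the neutrophil and endothelial lists 0.36 and -0.17, and without KO A the endothelial list -0.060. In DESeq2 0 of 12 markers of T, B and NK cells passed and 0 in limma, with Cd79b at -1.30 and Cd4 at -1.41 in the authors' deposited table (unadjusted p = 0.184 and 0.230). The median of that list, -0.69 against 0.74 for random lists (adjusted permutation p = 0.0278; camera with an estimated correlation, adjusted p = 0.690), turned to 0.056 with total-count scaling and was -0.20 without WT A and -1.01 without WT B, from low counts throughout.

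The secretory and metabolic programme of hepatocytes was lower in KO at the authors' size factors. All 25 tested acute phase proteins fell (25 adjusted over the list alone), with a median of -2.43 against -0.85 for matched random lists (adjusted permutation p = 0.0006; camera with an estimated correlation, adjusted p = 0.492, on the 10 recovered members). The log2 changes of Orm2 and Crp were -4.10 ± 0.22 and -4.11 ± 0.23 (SE) in the authors' deposited table, and those of Saa1 and Saa2, which share reads, -9.64 and -10.02. Of 25 hepatocyte secreted and identity genes 2 rose and 20 fell (2 and 21 adjusted over the list alone), with a median of -1.81 against -0.81 (adjusted permutation p = 0.00162; camera with an estimated correlation, adjusted p = 0.492, on 8 recovered members). The retinol carrier Rbp4 fell by 2.65 ± 0.20 in the authors' deposited table, and the near-identical antitrypsin genes Serpina1a, Serpina1c and Serpina1b stood at -3.32, -3.56 and -2.90. Of 25 cytochrome P450 and xenobiotic genes 4 rose and 16 fell (4 and 17 adjusted over the list alone), with a median of -1.52 against -0.74 (adjusted permutation p = 0.0099; camera with an estimated correlation, adjusted p = 0.618). Cyp2j5, Cyp3a25, Cyp2d9 and Cyp2e1 fell, with log2 changes of -4.20, -3.54, -3.43 and -2.82 in the authors' deposited table, with some uncertainty from related genes. The medians of these lists stayed negative with total-count scaling, at -1.498, -0.14 and -0.76 in limma, with 0 higher and 9 lower of 10 acute phase proteins, 3 and 4 of 8 hepatocyte genes and 6 and 11 of 19 cytochrome P450 genes.

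Genes of bile acid, glucose, amino acid and fatty acid breakdown pathways were also mostly lower in KO, and those of lipid synthesis and storage were split. Of 26 genes of bile acid and cholesterol metabolism 2 rose and 18 fell (2 and 18 adjusted over the list alone), with a median of -1.60 against -0.31 (adjusted permutation p = 0.0006; camera with an estimated correlation, adjusted p = 0.492). Log2 changes were -7.16 ± 0.24 and -5.81 ± 0.26 (SE) for the bile acid hydroxylases Cyp7b1 and Cyp8b1, -6.92 ± 0.39 for the uptake transporter Slco1a1 and -3.92 ± 0.21 for the sterol exporter Abcg8 in the authors' deposited table. Of 28 genes of gluconeogenesis and amino acid catabolism 0 rose and 27 fell (0 and 27 adjusted over the list alone; limma gave 0 and 10 among 11 recovered members), with a median of -2.58 against -0.91 (adjusted permutation p = 0.0006; camera with an estimated correlation, adjusted p = 0.492). Pck1, the control point of gluconeogenesis, stood at -3.77, Fbp1 at -3.34, the urea cycle enzyme Arg1 at -2.91 and Bhmt at -3.72 in the authors' deposited table. Of 24 genes of fatty acid oxidation and ketogenesis 3 rose and 20 fell (3 and 20 adjusted over the list alone), with a median of -1.21 against -0.68 (adjusted permutation p = 0.0461; camera with an estimated correlation, adjusted p = 0.575). Ppara, the nuclear receptor that drives this programme, stood at -2.52 and Acaa2 at -1.81, whereas Acot1 rose by 2.78 in the authors' deposited table. Lipogenesis and lipid storage genes split into 7 higher and 8 lower of 26 (7 and 8 adjusted over the list alone), with a median of 0.09 (adjusted permutation p = 0.109) that turned to -0.0085 in limma, -0.036 without KO A and -0.28 without WT B. Mttp, which loads lipid onto lipoproteins, stood at -1.63, G0s2 at -1.66, Dgat2 at -1.24 and Thrsp at -2.66 in the authors' deposited table. With total-count scaling the limma medians were -0.58 for bile acid and cholesterol metabolism (4 higher and 13 lower), -1.35 for gluconeogenesis and amino acid catabolism (0 and 9), -0.28 for fatty acid oxidation (4 and 10) and 0.81 for lipogenesis (15 and 3). The cholangiocyte markers moved opposite to the lists that fell, with a median of 2.83.

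Interferon and inflammatory genes were not apart from genes of like expression. Of 27 interferon-stimulated genes 6 rose and 5 fell (6 and 5 adjusted over the list alone), with a median of 0.11 (adjusted permutation p = 0.742). The antiviral genes Oasl1 and Rsad2 rose by 3.45 ± 0.30 and 2.86 ± 0.37 (SE) and Usp18 by 1.55 ± 0.26 in the authors' deposited table, while Irf9, part of the interferon-activated transcription complex, fell by 1.39 ± 0.26. Of 23 inflammatory cytokines, chemokines and their regulators 8 rose and 3 fell (8 and 3 adjusted over the list alone), with a median of 0.31 (adjusted permutation p = 0.876) that was -0.0066 without WT A and -0.014 among genes above the median mean count. With total-count scaling limma called 13 interferon-stimulated genes higher and 1 lower, and 11 inflammatory genes higher and 2 lower. Over all genes that fit called 8258 of 14073 higher and 1064 lower. The NF-κB subunits Relb and Nfkb2 rose by 2.45 and 1.21 and the adhesion molecule Vcam1 by 1.47, and the chemokine Ccl9 fell by 2.94 in the authors' deposited table. Over the 27 tested lists 15 lay apart from matched random lists, and camera called 16 with a preset correlation. With an estimated correlation camera called 0 (adjusted p from 0.492 to 0.926). At an unadjusted p under 0.05 it gave 2, those of gluconeogenesis and of cholangiocyte markers. That setting has few degrees of freedom here. For gluconeogenesis the estimated correlation of 0.0095 was close to the preset 0.01, yet the camera p rose from 9.66e-06 to 0.0472. A lack of calls by it therefore does not argue against a list. Where DESeq2 called 0 members of a list in 1 direction, the count at an unadjusted p under 0.05 was also 0, except for 1 endothelial rise (Lyve1) and 1 stellate fall (Ecm1), which were named after their values were seen.

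**Figure D2:**
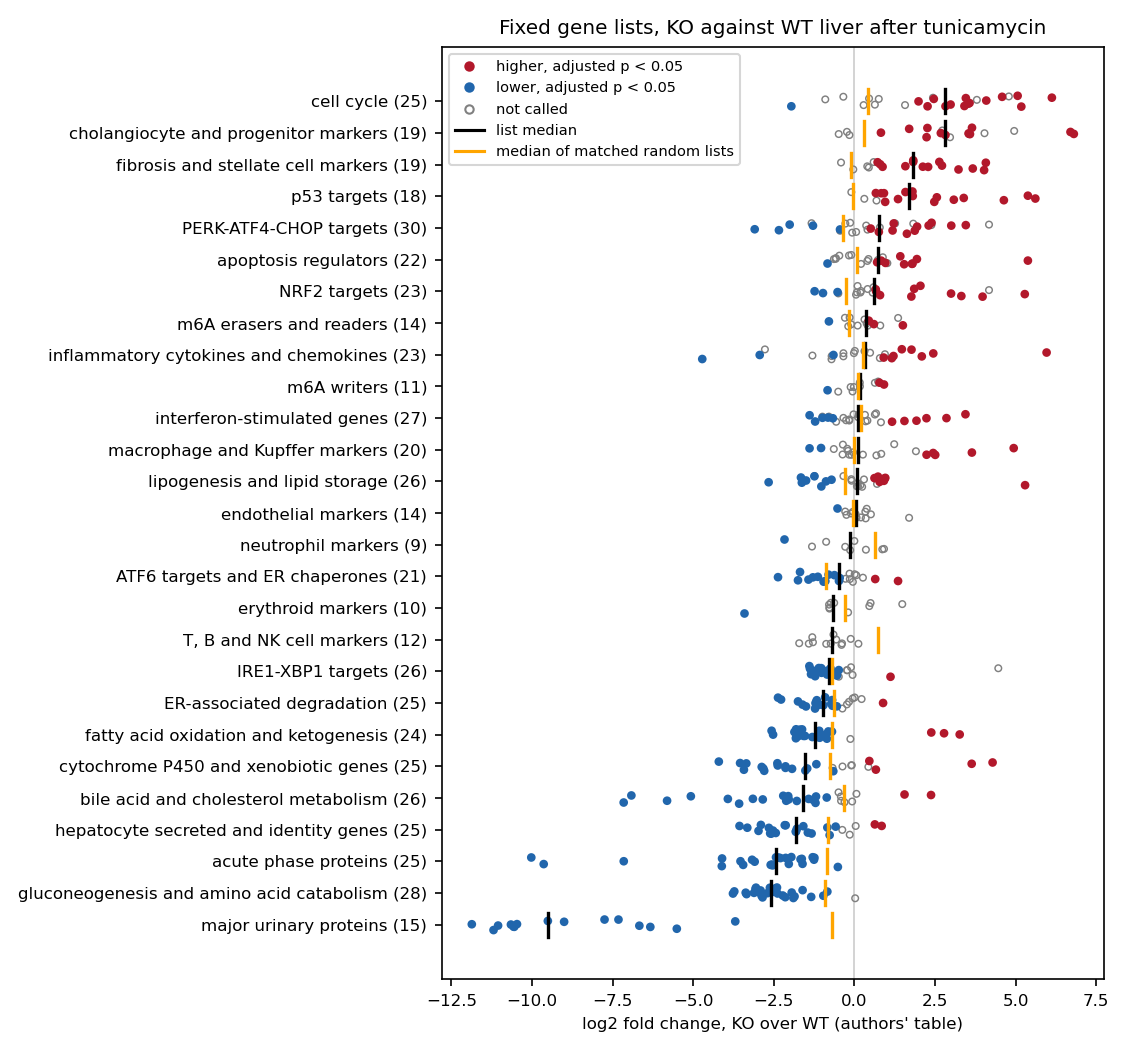
Log2 change in KO over WT of each tested member of 27 gene lists, from the authors' deposited table, with the number tested in brackets, black bars at list medians and orange bars at the median of matched random lists. Cell cycle and cholangiocyte lists had medians of 2.83 and the Mup list one of -9.51; with total-count scaling the medians of the IRE1, ATF6, neutrophil, lymphocyte and erythroid lists turned positive.

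The peak lists address which mRNAs were bound by the m6A antibody in each genotype. The WT list held 5586 peaks in 2988 genes and the KO list 12290 peaks in 5861 genes. Peaks covered 517 kb in WT and 1812 kb in KO, with median widths of 49 and 99 bp. The median enrichment score was 24.2 in WT and 13.1 in KO. Enrichment scores are the authors' own, 1 per peak and genotype, with no value per library, so peaks were not tested across replicates. The highest scores of the WT list were of peaks in Ell2 (6283), Dpyd (5286), Lgr4 (4526), Cyb5r3 (4304) and Hgsnat (3956). Those of the KO list were of peaks in Susd6 (2103), Dip2c (944), Glud1 (876), D15Ertd621e (875) and Ash2l (599). The highest scores did not always carry the smallest p: the authors' p of the Lgr4 peak was 3.23e-23, and that of a WT peak in Hspa5 with a score of 21.3 was 0. Input reads per peak are not given, so a high score may rest on few of them. Both lists held peaks in 2731 genes, the WT list alone in 257 and the KO list alone in 3130. By score, the first genes with a WT peak alone were Cox11, Setd1b, Sox13, Rnaset2a and Chst13, and with a KO peak alone Dip2c, D15Ertd621e, Ash2l, A130010J15Rik and Tmem64.

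Of the WT peaks, 4065 (72.8%, exact 95% interval 71.6 to 73.9) were overlapped by a KO peak, and of the KO peaks 3361 (27.3%, 26.6 to 28.1) by a WT peak. Intervals cover counting error only. The excess of KO peaks shrank to 1.34 per WT peak among peaks with a p at or below 5.19e-11 in either list, 3823 in WT and 5115 in KO.

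WT peaks without a KO peak lay mostly away from gene starts. Near the 5′ end of genes, within 1000 bp of the annotated start, 153 of 1725 WT peaks (8.87%, exact 95% interval 7.57 to 10.3) had no overlapping KO peak. Within 1000 bp of the annotated gene end this was so for 546 of 1160 (47.1%, 44.2 to 49.99), and farther from both for 743 of 2395 (31.0%, 29.2 to 32.9). The ends differed by 38.2 percentage points (35.0 to 41.4; two-sided Fisher's exact test, p = 4.87e-123). Among peaks as a whole 32.3% of WT and 31.2% of KO peaks lay near the gene start and 21.7% and 18.1% near the gene end. Shares in untranslated regions, distance to the stop codon and sequence motifs were not analysed here.

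**Figure D3:**
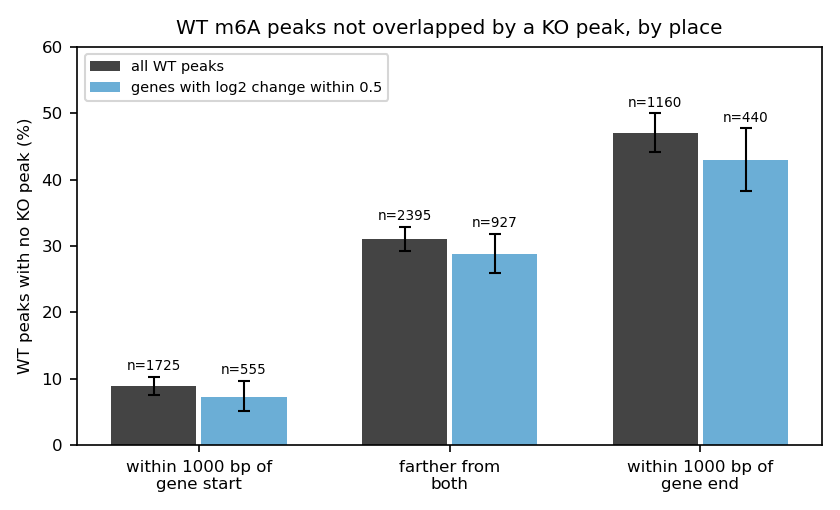
Percent of WT peaks with no overlapping KO peak by place in the gene, for all WT peaks and for genes with a mean count of at least 100 and a log2 change within 0.5, with exact 95% intervals. The share was 8.87% near the gene start and 47.1% near the gene end, and 7.21% and 43.0% in genes with little change in mRNA.

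Ddit3 carried peaks near both ends in both genotypes, with the higher score near the gene end in WT and on a peak reaching from the gene start in KO. Ddit3 lies on the plus strand of chromosome 10 from 127290793 to 127296291 (mm10), and coordinates are given as the lists have them. In the WT list a peak near its end, from 127295998 to 127296191, scored 14.5 and one at its start, from 127290841 to 127290890, scored 1.97. In the KO list a peak of 3 blocks from 127290841 to 127295368 scored 9.89 and a 49 bp peak near the end, from 127296142 to 127296191, scored 2.43. Among the 30 tested PERK targets 15 had a WT peak and 22 a KO peak, 0 a WT peak alone and 7 a KO peak alone. Those 7 were Asns, Atf3, Gdf15, Ppp1r15a, Psat1, Slc7a5 and Wars. Over all 14257 tested genes 3130 had a KO peak alone, a share close to that of this list, and 257 had a WT peak alone. In Chac1, which degrades glutathione, and in Eif4ebp1, a brake on translation, the WT peak lay near the gene end and the KO peak near the start, without overlap. Atf4 had a KO peak from 80257200 to 80257496 on chromosome 15, near its end, where the WT list had none.

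**Figure D4:**
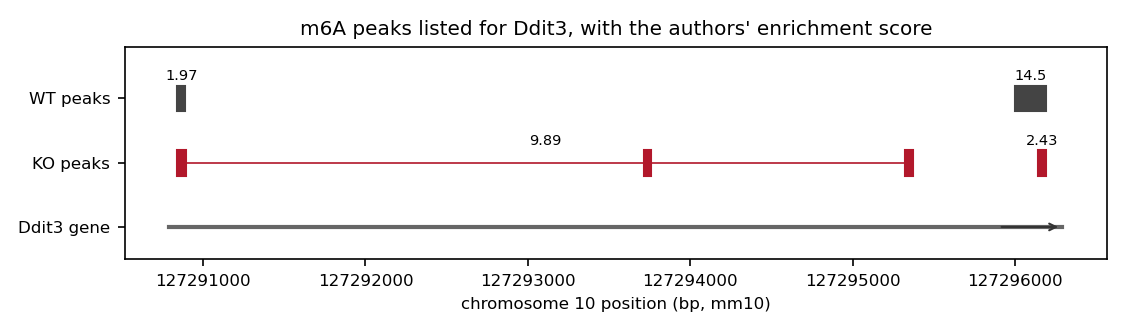
Position in bp on chromosome 10 (mm10) of the peaks listed for Ddit3 in WT (grey) and KO (red), with each peak's score from the authors' own list, and blocks of 1 peak joined by a line. The higher score was at the gene end in WT (14.5) and at the peak reaching from the gene start in KO (9.89).

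The last comparison asks whether genes whose peaks differed by genotype also differed in mRNA. The 257 genes with a WT peak alone had a median log2 change of -0.82, with 11 higher and 155 lower in KO, the 2731 with peaks in both lists one of -0.51, the 3130 with a KO peak alone 0.12, and the 8139 with no peak 0.26. Within bins of mean expression genes with a WT peak alone lay below those with both, by a difference of medians of -0.50, and genes with a KO peak alone lay above those with both by 0.45. Each of these permutation tests gave p = 1e-05, the smallest that 100000 permutations can give (adjusted over 5 comparisons, 1.25e-05). Genes with peaks in both lists and genes without peaks differed by -0.02 at equal mean expression (permutation p = 0.731), while without bins the difference was -0.77 and between means 0.44. These tests cannot tell whether m6A went with mRNA level: a change in mRNA itself helps to decide in which genotype a peak is called, so the classes depend on the outcome compared. The sign of the table was also read from these peak lists, and genes are not independent replicates.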

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

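The fits by limma, total-count scaling, leaving out single libraries, camera, the bounds of 500 and 2000 bp, the fits without bins and the restriction to genes or peaks of 1 kind for the place of peaks were chosen after the data were seen; all others were planned. Named genes and lists gave 806 further values that kept direction and, where a test was compared, side of the threshold. Another 211 kept direction and changed side, and the reversals are given here. For list medians in limma only the direction was compared. Named genes above the median mean count kept their deposited fold change, so their direction was fixed beforehand. Of whole comparisons 40 values were also the same. No paired analysis was possible because recovered libraries carry no replicate number. The replicate block, DESeq2 and upper-quartile scaling of counts, a fit without a filter, motif windows and a limit to exons or 3′ untranslated regions were not run, since they need numbered counts, a genome or transcript models. The cause of each change was not tested, except that fewer genes or libraries entered some of them. The shift under total-count scaling is an exception too. Summed normalized counts had a log2 ratio of -0.82, KO over WT. Scaling to equal totals therefore moves all but low counts upward in KO by about that size. The 50 genes with the highest mean held 23.85% of KO and 32.8% of WT counts.

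Genes higher in KO numbered 1402 among genes above the median mean count and 8258 with total-count scaling. Genes lower in KO numbered 1801 with an at least 2-fold change and 1064 with total-count scaling. Without single libraries limma called 0 to 3788 higher and 0 to 3437 lower, with 0 without KO A (5066 at an unadjusted p under 0.05) and 0 without KO B (5407). Camera with an estimated correlation called 0 lists, against 15 by random lists (2 at an unadjusted p under 0.05). With its few degrees of freedom it could hardly call any.

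With total-count scaling Mettl14 turned to 0.32, Zc3h13 to 0.76, Zcchc4 to 0.85, Pcif1 to 0.70, Xbp1 to 0.085, Dnajb9 to 0.080, Hnrnpc to 0.033 and Clec4g to 0.27, and the medians of the IRE1 list to 0.057, ATF6 to 0.044, T, B and NK cells to 0.056, neutrophils to 0.78 and erythroid cells to 0.22. The median over all genes of the total-count fit was 0.87, so a change of sign there need not set a gene or list apart. Zcchc4 was also positive in limma (0.0350, and 0.0357 with a pseudocount of 0.1). Among genes above the median mean count the inflammatory list had a median of -0.0137 and the macrophage list one of -0.090. The lipogenesis list had -0.00851 in limma and -0.00850 with a pseudocount of 0.1. Without single libraries Zcchc4 ranged from -0.33 (without WT B) to 0.40 (without WT A), Atf4 from -0.42 (without WT A) to 0.77 (without WT B), and list medians from -0.00658 (WT A) to 1.16 (WT B) for inflammatory genes, -0.28 (WT B) to 0.19 (WT A) for lipogenesis, -0.61 (WT A) to 0.41 (KO B) for neutrophils, -0.17 (WT B) to 0.28 (WT A) for endothelial cells and -1.38 (KO A) to 0.69 (KO B) for erythroid cells.

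The share of WT peaks with a KO peak was 70.6% at an enrichment of at least 4, 70.3% with an overlap of at least 0.5 of the shorter peak, 59.9% for equal numbers of top peaks and 91.4% by genes. The share of KO peaks with a WT peak was 43.5% among peaks with a p at or below 5.19e-11, 26.1% at an enrichment of at least 4, 47.5% for equal numbers and 46.6% by genes; KO peaks per WT peak fell to 1.34 at that p. WT peaks near the gene start without a KO peak made up 18.9% for equal numbers, 14.5% at that p and 7.26% within 500 bp, and those near the gene end 59.4% for equal numbers. KO peaks near the gene start made up 45.4% of the top peaks. Genes with peaks in both lists less genes without peaks gave 0.030 above the median mean count (permutation p = 0.593), 0.44 for means (p = 5e-05, the smallest that 20000 permutations can give), -0.77 without bins and -0.18 at the smaller p (permutation p = 7.5e-04).

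Counts of Mettl14, at 62.0 to 99.7, and of lymphocyte and neutrophil markers were low, which leaves larger changes detectable: Relb, with counts of 22.9 to 134, was called. IP depth is not given in the sources used here.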

Other observations

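All tests of explanations, the comparisons between libraries of a genotype and the genes Elovl3, Cyp4a12a, Cyp2b9, Cyp2b13, Ghr, Igf1, Socs2, Ddx3y, Xist and Lcn2 were chosen only after the results were seen. Tk1, Lyve1 and Ecm1 were also named after their values were seen. Other genes were named by the rule or as list members. The gene lists and the limits on p and enrichment of peaks were planned. Several genes known to differ by sex in the liver under control of growth hormone were among those called, named here without a count or test of such genes as a group, and beside a general fall of hepatocyte lists. In the authors' deposited table the fatty acid elongase Elovl3 was lower by a log2 change of -6.68 and Cyp4a12a by -2.202, beside the Mup genes, Slco1a1 (-6.92) and Cyp7b1 (-7.16), and the female-biased Cyp2b9 and Cyp2b13 were higher by 4.29 and 3.37, with some uncertainty from related genes. The growth hormone receptor gene Ghr stood at -1.10, its target Igf1 at -2.37 (adjusted p = 6.28e-26) and Socs2, which is both a target and an inhibitor of this pathway, at 2.56 in the authors' deposited table. All 4 input libraries carried the Y-linked Ddx3y, with normalized counts of 439 and 449 in KO and 746 and 624 in WT, and hardly any Xist (at most 2.16).

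Some gene lists also differed between the libraries of a genotype, in either direction. Only recovered members with a mean count of at least 10 were compared. Neutrophil markers had a median log2 ratio of 1.09 between WT B and WT A, with 7 of 8 recovered members higher in WT B, acute phase proteins one of 0.65 and IRE1 targets one of 0.39 (24 of 24 higher). The ATF6 list had -0.016 (4 of 9 higher), the erythroid list -0.87 and the Mup list -0.997. Between KO B and KO A the erythroid list had -1.11 and the Mup list -0.90, the neutrophil list -0.34, the acute phase list 0.27 and the IRE1 list 0.072, and 5 of 23 cell cycle genes were at least 2-fold apart. Lcn2, an acute phase gene, had normalized counts of 6406 in WT A and 17905 in WT B, and of 2297 and 2667 in KO. Over all 12663 recovered genes with a mean of at least 10 the median was 0.00 between the WT libraries, and 417 were at least 2-fold higher in WT B. That count leaves out genes higher in WT A, while the 392 genes at least 2-fold apart in KO were counted in both directions. The labels give no difference between libraries of a genotype.

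Loss of a writer would leave fewer m6A peaks, but the KO list held 12290 and the WT list 5586. The number of KO peaks per WT peak followed the change in mRNA: among genes with a mean count of at least 100 it was 7.42 at a log2 change over 1 and 1.07 at one under -1. Since the sign of the change was read from these peak lists, the direction of that relation was fixed beforehand. A higher level of the mRNAs in KO as the whole cause is argued against by the 3884 such genes with a log2 change within 0.5, which had 2.55 KO peaks per WT peak, and by the 2850 within 0.5 by total-count scaling, which had 1.66. More sensitive detection in the KO libraries cannot be told apart. Among the genes with little change the ratio was 2.92 times higher in the lowest than in the highest tertile of mean expression (5.81 against 1.99), but by total-count scaling 1.48 times (2.11 against 1.42). The ratio over all peaks fell to 1.34 among peaks with a p at or below 5.19e-11 but was 2.24 at an enrichment of at least 4, and KO peaks without a WT peak had a median enrichment of 12.98, close to the 13.55 of the other KO peaks. Scores were lower in the KO list, with a median enrichment of 13.1 against 24.2 in the WT list. For peaks found in both lists the medians were 13.55 in KO and 30.1 in WT. In the genes with little change they were 13.9 and 34.5. IP depth, the peak caller and antibody binding to unmethylated RNA were not tested, and a real gain of m6A stays open.

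WT peaks without a KO peak were more frequent near gene ends, where m6A is known to be dense, than near gene starts. Lower mRNA of the genes is argued against, since the gap was 35.7 percentage points (30.6 to 40.8) in genes with little change in mRNA, and 46.2 (41.1 to 51.3) in those with little change by total-count scaling. Lower enrichment scores near gene ends as the whole cause are argued against, since a gap remained within each tertile of enrichment. From the lowest to the highest tertile it was 46.1, 33.3 and 18.2 points (12.2 to 24.2 in the highest). The gap thus shrank as enrichment rose, and it was 45.1 points among peaks of the smallest width and 22.2 among wider ones. Peak strength may account for part of it, and the score does not fully measure how readily a peak is detected. Poorer coverage of gene ends in KO libraries cannot be told apart, as 18.4% of KO peaks without a WT peak lay near gene ends against 21.7% of all WT peaks, and coverage was not analysed here. A loss of m6A itself stays open and was not tested.

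Of 19 cholangiocyte and 19 stellate cell markers 12 and 14 were called higher in KO. Of 25 hepatocyte secreted and identity genes 20 were called lower. A lower share of hepatocytes alone would raise the markers of every other cell type, and is argued against by the endothelial list: the cholangiocyte median lay above it by 2.77 on the log2 scale (two-sided permutation p = 0.0036, 19 and 14 genes). Genes are not independent replicates, so that p may be too small. Camera estimated a correlation of 0.51 within the endothelial list and of -0.0098 within the cholangiocyte list. Both medians had been seen before they were compared. With total-count scaling the limma medians were 0.90 for endothelial markers (12 of 14 called higher) and 3.19 for cholangiocyte markers (15 of 19). That fit called 8258 of 14073 genes higher. The cholangiocyte list lay above the endothelial list by either scaling, but a lower share of hepatocytes as part of the cause stays open. More cholangiocytes or progenitor cells in KO tissue may account for the 12 markers called higher, but a rise of the same genes within hepatocytes cannot be told apart in bulk RNA. Among markers of that list Spp1, also a macrophage gene, had normalized counts of 3311 and 2460 in KO and 527 and 696 in WT. Krt19 was less abundant, with 163 and 210 in KO and 16.2 and 14.8 in WT. The median of the mean count over tested genes was 211. The deletion itself, as a cause of either, stays open and untested.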
